A study of Mus musculus with 6 samples.

How the data were processed

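Retinal total RNA from mice at postnatal day 7, in 3 wildtype and 3 knockout samples, was hybridised to Affymetrix arrays by the submitters. The deposited values are linear probe set intensity values, 1 per probe set and array, made with MAS5 per the submitters' processing notes. No version, scaling target or detection call is given in the sources used here. The trimmed means of the arrays differed, so the deposited intensity values had not been brought to a common level. Groups were taken from the labels. Nothing in the labels says whether an array held RNA of 1 animal or several, so p-values measure the spread between these samples, which may be partly technical.

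The choices in this paragraph were made before the data were examined. The 64 control probe sets were left out. Each array was scaled to the same mean after trimming 2% at each end. A pseudocount of 19.1, the 20th percentile of all signals, was added before taking log2, so fold changes of dim probe sets are understated. Probe sets with a mean signal above the 40th percentile were tested, which left 13575. Knockout minus wildtype was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, followed by Benjamini-Hochberg adjustment. Gene lists were written beforehand (34 lists), and those with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, using the probe set of highest mean signal for each gene. Camera with an estimated correlation and fry were run beside it. Single values per array were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3.

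Probe sets were named from the platform annotation, with symbols updated through Entrez gene identifiers, of which 20364 matched. A single symbol was found for 20380 non-control probe sets, several for 691 and none for 1555. A probe set with several symbols was not named as 1 gene, and one with none is unnamed here. The targeted gene, and the planned results that need it, are not reported here. Named genes followed a fixed rule: genes past the threshold, up to 12 per direction, filled up where fewer passed with the smallest unadjusted p among named genes with at least 1.5-fold change and groups that did not overlap, then up to 4 members of each list by the size of the moderated statistic (2 are given), and the sex-linked and control genes. The number of 2 members per list was set after the alternatives had been run. Probe sets whose identifiers end in _x_at, _s_at or _a_at can hybridise with related transcripts.

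The fit was tested on simulated arrays in 20 runs, with 200 of 13575 probe sets changed. Means were those of the real probe sets, and variances were drawn from the distribution that limma fitted over all of them. The noise was normal and independent, as the fit assumes, and no simulated array stood apart. The shares below hold under that model and may differ for the real arrays. It recovered 4.8% of 1.5-fold, 47.2% of 2-fold, 89.8% of 3-fold and 96.8% of 4-fold changes, and 4.25% of its calls were false. Alternatives covered normalization, pseudocount, filter, variance model, array weights, the replicate number as a block, each array left out in turn, and covariates for the lens list and Xist signal. The lens covariate was run because that list differed between arrays by 2.19 on the log2 scale, and those of muscle, blood and pigment cells were not, at 0.51, 0.52 and 0.91. The Xist covariate was run because a Uty probe set differed by 1.25.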

Results

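Retinal RNA from mice at postnatal day 7 was measured on 6 Affymetrix arrays. Per the labels, 3 arrays came from C57BL/6 wildtype mice and 3 from knockout mice. The strain background of the knockout mice is not stated here, and a strain difference was not separated from the knockout. The table held 22690 probe sets, of which 22626 were not controls. The trimmed mean signal per array, before rescaling, was 215, 171 and 312 in the wildtype arrays and 304, 277 and 263 in the knockout arrays. The comparison asks which retinal transcripts differ between the knockout and wildtype mice at an age when the retinal layers are still maturing. The small number of arrays limits the precision of every value below.

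Of 13575 probe sets tested, 2 had a Benjamini-Hochberg adjusted p under 0.05 in limma, and both were lower in the knockout arrays. The first, the brighter in wildtype, had a scaled signal of 577 ± 112 (SD, n = 3) in wildtype and 63.6 ± 22.1 in knockout retinae. That is a 9.07-fold lower mean signal, and its log2 fold change was -2.87 ± 0.23 (SE; limma adjusted p = 0.0052). The second had a scaled signal of 529 ± 167 (SD, n = 3) in wildtype and 87.3 ± 2.63 in knockout retinae, a 6.06-fold lower mean. Its log2 fold change was -2.32 ± 0.23 (SE; limma adjusted p = 0.017). For each of them, all 3 knockout arrays lay below all 3 wildtype arrays. Both are unnamed here, because the probe annotation used does not list them, and their identifiers are printed in the figures. The labels were not checked against the signal of a gene known to differ. Without wildtype array 3, neither probe set passed (limma adjusted p = 0.13 and 0.42), although the log2 fold changes were -2.71 and -2.26. A separate equal-variance statistic per probe set called 0 probe sets, with 492 at an unadjusted p under 0.05.

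**Figure D1:**
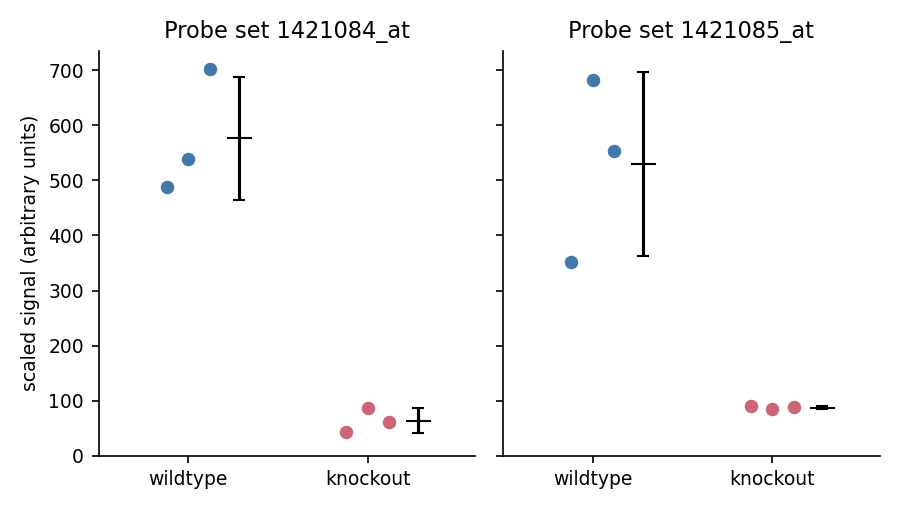
Scaled signal (arbitrary units) of the first (left) and second (right) unnamed probe set in each array. Points are the 3 wildtype and 3 knockout arrays, and the black bars give the group mean and SD; every knockout array lies below every wildtype array.

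**Figure D2:**
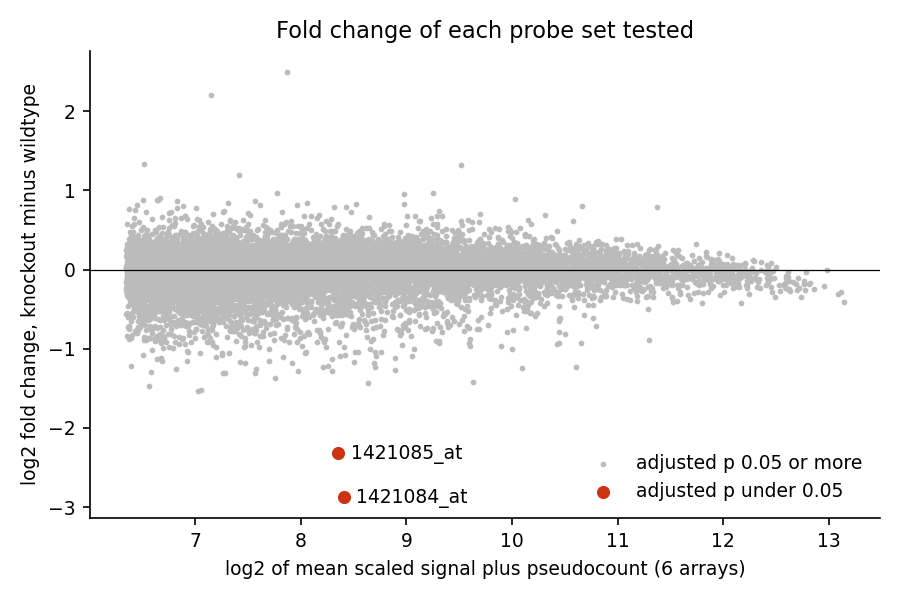
Log2 fold change, knockout minus wildtype, against the log2 of the mean scaled signal plus the pseudocount, for 13575 probe sets (points). The 2 labelled probe sets are those with an adjusted p under 0.05.

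No probe set with a gene name passed the test. The smallest adjusted p of a named gene was 0.999. An unadjusted p under 0.05 was reached by 518 probe sets, where 679 would be expected by chance. A change of at least 1.5-fold with groups that did not overlap was found for 219 probe sets, 34 higher and 185 lower in the knockout. Non-overlap alone held for 9.1% of probe sets, where chance gives 10%. The split by direction depended on the scaling: it was 73 higher and 106 lower with median scaling, and 350 higher and 14 lower without rescaling. It also depended on knockout array 1, with 60 higher and 94 lower when that array was left out. Without rescaling the median log2 fold change of all probe sets was 0.29.

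Among named genes with at least 1.5-fold change and groups that did not overlap, the 12 smallest unadjusted p values in each direction are given as values that did not pass the test (limma adjusted p = 0.999 for each). With positive log2 fold changes, Trim32, an E3 ubiquitin ligase, had a scaled signal of 328 ± 79.5 in wildtype and 643 ± 96.6 in knockout (SD, n = 3), a log2 fold change of 0.95 ± 0.21 (SE). Map2k2, a kinase of the ERK pathway, had 250 ± 35.1 and 424 ± 17.6 (log2 fold change 0.72 ± 0.16), and its other tested probe set had 0.03. Nell2, a secreted neural glycoprotein, had 126 ± 27.0 and 273 ± 99.7, and a second Nell2 probe set had a log2 fold change of 0.89. The log2 fold changes of Vdac1, Prkrip1, Vapb, Cd47, Polr2a, D030056L22Rik, Lztr1, Samd10 and Hip1r lay between 0.68 and 0.97.

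With negative log2 fold changes, Scd2, a stearoyl-CoA desaturase, had a scaled signal of 407 ± 57.2 in wildtype and 185 ± 76.9 in knockout (SD, n = 3), a log2 fold change of -1.13 ± 0.27 (SE). Its other tested probe sets had -0.12 and -0.76. Dpysl3, of the collapsin response mediator family, had 253 ± 24.5 and 149 ± 5.56 (log2 fold change -0.69 ± 0.16), while its other tested probe sets had 0.19 and -0.01. Rab3c, a synaptic vesicle GTPase, had 175 ± 48.0 and 80.1 ± 22.7, and its second probe set had -0.53. The log2 fold changes of Srsf2, Uba7, Ykt6, Ptprs, Rbbp4, Dck, Sec61a1, Hipk3 and Bcat1 lay between -1.30 and -0.82. Of the 24 genes, 20 had another tested probe set, and 21 of those 33 probe sets had the same sign. That count includes values near 0, such as 0.03 for Map2k2 and Vapb. Those at least 1.5-fold in the same direction were of Nell2 (0.89), Scd2 (-0.76) and Sec61a1 (-0.64). The only other tested probe sets of Polr2a (-0.16), Lztr1 (-0.28) and Ptprs (0.23) had the opposite sign.

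None of the 30 gene lists with at least 5 tested members passed an adjusted p of 0.05 in limma's camera with a preset correlation. At an unadjusted p under 0.05, camera gave 5 lists, camera with an estimated correlation gave 0 and fry gave 1. The lowest adjusted p was 0.15 in camera with the preset correlation, 0.82 with the estimated one and 0.92 in fry. Over all 512 list memberships, 0 passed over all probe sets and 0 passed when adjusted over the list alone. The members named below did not pass the test, and their log2 fold changes are given as values.

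Of the photoreceptor lists, 7 of 22 rod genes had positive and 15 negative log2 fold changes (camera p = 0.018, adjusted p = 0.15; p = 0.22 with an estimated correlation). The rod list means were -0.081, 0.083 and 0.076 in wildtype and -0.18, 0.10 and -0.0020 in knockout arrays 1 to 3 (exact two-sided permutation p = 0.7), lowest in knockout array 1. The rod genes Rom1 and Sag, encoding a disc rim protein and arrestin, had -0.34 and -0.18. Of 11 cone genes, 3 had positive and 8 negative values (camera p = 0.019, adjusted p = 0.15; p = 0.069 with an estimated correlation; fry p = 0.039). The cone opsin Opn1mw had -0.85 (95% interval -1.67 to -0.03; -0.45 without knockout array 1), and the thyroid hormone receptor Thrb had -0.44. The mean log2 fold change of the cone list was -0.16, and all 3 knockout arrays lay below all 3 wildtype arrays (exact two-sided permutation p = 0.1, the smallest possible). The array means of 2 of the 30 tested lists, cone and Mueller glia, did not overlap between the groups, where chance gives 10%. Of 14 photoreceptor precursor genes, 6 had positive values, with Aipl1 at -0.26 and Cdhr1 at -0.19 (adjusted p = 0.29).

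Retinal progenitor genes had positive values in 13 of 16 cases (camera p = 0.020, adjusted p = 0.15; p = 0.23 with an estimated correlation), with Six3 at 0.39 and Notch1 at 0.36. The list mean was 0.23 in knockout array 1 but -0.024 and -0.029 in knockout arrays 2 and 3, against -0.098, 0.036 and -0.11 in wildtype (exact two-sided permutation p = 0.3). Cell cycle genes had positive values in 7 of 21 (camera p = 0.038, adjusted p = 0.23; p = 0.25 with an estimated correlation), with the mitotic checkpoint kinase Bub1b at 0.88 (0.47 without wildtype array 2) and the ribonucleotide reductase subunit Rrm1 at -0.83 (-0.24 without knockout array 1). Of the inner retinal lists, positive values were found for 8 of 17 bipolar (Gng13 0.46, Irx5 0.36), 7 of 16 ganglion (Nefh 0.58, Nefl 0.26), 7 of 15 amacrine (Gjd2 -0.49, Neurod2 0.43) and 6 of 9 horizontal cell genes (Septin4 0.31, Lhx1 0.29). Their camera adjusted p values lay between 0.72 and 0.96. Synapse genes had positive values in 9 of 23 (adjusted p = 0.46), with the vesicle protein Vamp2 at 0.52 and the calcium sensor Syt1 at -0.998 (-0.35 without knockout array 1).

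Mueller glia genes had positive values in 14 of 20 (adjusted p = 0.25), with the potassium channel Kcnj10 at 0.46 and Dbi at 0.18. Reactive glia genes had positive values in 4 of 11 (adjusted p = 0.72), with Cebpd at -0.23 and Gfap at 0.19. Microglia and macrophage genes had positive values in 13 of 18 (adjusted p = 0.25), with the complement gene C1qb at 0.41 and the chemokine receptor Cx3cr1 at 0.35. The list mean was 0.31 in knockout array 1 but -0.046 and -0.090 in knockout arrays 2 and 3, against -0.088, 0.093 and -0.17 in wildtype (exact two-sided permutation p = 0.6). Complement and antigen presentation genes had positive values in 7 of 11 (adjusted p = 0.94), with Serping1 at 0.28. Vascular genes had positive values in 12 of 18 (adjusted p = 0.89), with Rgs5 at 0.30 and Eng at -0.44, and astrocyte genes in 4 of 7 (adjusted p = 0.94), with Slc1a2 at -0.35 and Gja1 at 0.68.

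Of 38 oxidative phosphorylation genes, 15 had positive and 23 negative values (camera p = 0.0075, adjusted p = 0.15; p = 0.24 with an estimated correlation), with Sdhc at -0.37 and Atp5b at -0.29. Glycolysis genes had positive values in 11 of 20 (adjusted p = 0.72; Slc2a1 0.31, Pfkm -0.23), and their mean was positive where camera's direction was down. Cholesterol synthesis genes had positive values in 8 of 18 (adjusted p = 0.25), with Fdps at -0.67 and Msmo1 at -0.52. Ribosomal protein genes had positive values in 10 of 28 (adjusted p = 0.25; Rps27 -0.41, Rpl11 -0.22). Immediate early genes had positive values in 8 of 16 (adjusted p = 0.89), with Jund at 0.61 and Klf6 at 0.24. ERK feedback genes had positive values in 8 of 15 (adjusted p = 0.71), with Epha2 at 1.33 and Phlda1 at 0.46. Stress and heat shock genes had positive values in 10 of 24 (adjusted p = 0.44; Ddit3 -0.36, Calr 0.25), and apoptosis genes in 11 of 18 (adjusted p = 0.32; Tnfrsf1a 0.47, Casp9 0.37).

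Of a list of sodium pump genes and related genes, 3 of 8 had positive values (adjusted p = 0.62), with Fxyd7 at -0.16 and Fxyd1 at 0.24 (-0.18 without knockout array 1). Adhesion and matrix genes had positive values in 15 of 21 (adjusted p = 0.32), with the integrin Itgb1 at -0.44 and Crb1 at -0.33.

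**Figure D3:**
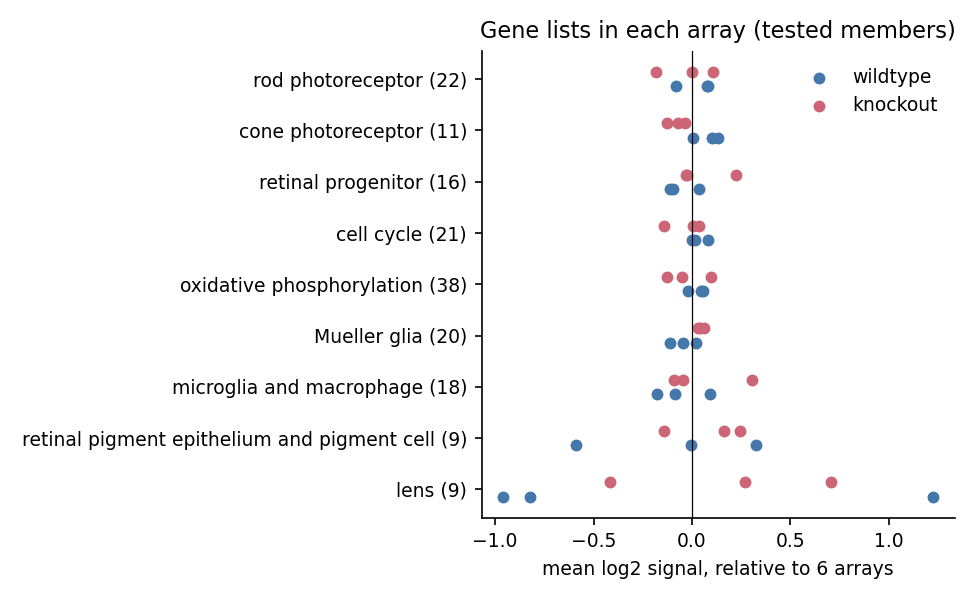
Mean log2 signal of 9 gene lists in each array, relative to the mean of the 6 arrays, with the number of tested members in parentheses. Points are arrays, coloured by group; the lens list spreads from -0.96 to 1.23 and is highest in a wildtype array.

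Lists of other tissues varied between arrays within each group. The lens list, which holds crystallins, had 9 of 9 positive values among its tested members (adjusted p = 0.25; p = 0.45 with an estimated correlation), but 9 of 11 lens probe sets below the filter had negative ones, and its array means were -0.96, -0.82 and 1.23 in wildtype and 0.27, -0.42 and 0.71 in knockout (exact two-sided permutation p = 0.7). Cryga had a log2 fold change of 0.80 (95% interval -0.65 to 2.25) and Crygf of 0.68. Pigment cell genes had positive values in 6 of 9 (adjusted p = 0.32), with Ttr at 0.70 and Dct at 0.34 (0.15 and 0.054 without wildtype array 2). The lists of skeletal muscle (Casq1 -0.33, Des -0.35), cornea and ciliary epithelium (Zic1 0.50, Krt18 -0.14), blood (Ngp -0.035) and the interferon response (Ifitm3 0.36, Irf1 -0.18) had 4, 3, 1 and 3 tested members and were not tested as sets. All 4 muscle genes had negative log2 fold changes, with array means of 0.15, 0.12 and 0.24 in wildtype and 0.0016, -0.27 and -0.24 in knockout (mean log2 fold change -0.34; exact two-sided permutation p = 0.1, the smallest possible).

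Knockout array 1 stood apart from the rest. Its correlation with the other arrays lay between 0.914 and 0.936, against 0.958 to 0.979 among the other 5, and the first principal component took 48.1% of the variance. The 3' to 5' ratio of the Actb control was 1.64, 1.44 and 1.59 in wildtype and 2.17, 1.69 and 1.90 in knockout arrays (exact two-sided permutation p = 0.1, the smallest possible). The Gapdh ratio was 0.98, 0.82 and 0.88 in wildtype and 1.18, 0.88 and 1.16 in knockout (exact permutation p = 0.2). The scaled 18S control signal was 2573 in wildtype array 2 and 609 in knockout array 1, against 38.8 to 54.9 in the other 4 arrays. The median signal before rescaling was 90.4 ± 22.8 in wildtype and 103 ± 5.15 in knockout (SD, n = 3; exact permutation p = 0.4).

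The Y-linked genes Eif2s3y, Kdm5d and Uty gave signal on all 6 arrays. Eif2s3y had 116 ± 31.3 in wildtype and 129 ± 41.8 in knockout, and a Uty probe set had 142 ± 47.2 and 114 ± 38.5 (SD, n = 3). Another Uty probe set above the filter had 113 ± 20.4 in wildtype and 118 ± 36.3 in knockout. Values given for Uty in the settings below are of the former probe set. Of 3 Xist probe sets, 2 stayed at or under 5.44 on every array and the third had 97.6 ± 29.1 and 89.4 ± 4.25. The sex-linked list had 4 of 8 positive values (camera adjusted p = 0.95), with the X-linked Kdm5c at 0.34.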

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

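Settings that leave out 2 arrays, and camera with an estimated correlation in each setting, were chosen after seeing the data, and the others were planned. The log2 fold changes of the first and second unnamed probe set kept their sign in every setting run, from -3.20 to -2.35 and from -2.58 to -1.95. The count of probe sets past the threshold was 2 with quantile or median scaling, either pseudocount, the stricter filter, no intensity trend, array weights, the sex-linked list left out and an adjusted p of 0.1. It was 10 without rescaling, 1 without a filter, 0 with the ordinary statistic, and 1 with the lens or the Xist covariate. It ranged from 0 to 4 when 1 array was left out: 0 without wildtype array 3, 4 without wildtype array 2, and 1 without knockout array 2 or 3. It was 4 without wildtype 2 and knockout 1, and 0 without wildtype 3 and knockout 3. The cause was not tested, apart from the fewer arrays.

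Call losses follow the same settings. The second had -2.32 without a filter (limma adjusted p = 0.093, where more probe sets were tested), -2.35 with the lens covariate (0.10) and -2.33 with the Xist covariate (0.23). With the ordinary statistic the first had -2.87 and the second -2.32 (adjusted p = 0.998 for each). Without wildtype 3 and knockout 3 they had -2.71 and -2.26 (0.89 for each). With 1 array left out they ranged from -3.06 to -2.67 and from -2.58 to -2.12, with adjusted p up to 0.13 and 0.42.

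The count of probe sets 1.5-fold apart without overlap (219) was 364 without rescaling, 126 with the higher pseudocount, 351 without a filter and 122 with the stricter one. It ranged from 154 to 767 with 1 array left out, where chance non-overlap is more frequent, and was 134 without wildtype 2 and knockout 1 and 670 without wildtype 3 and knockout 3. The count of gene lists past the threshold (0) was 3 without rescaling, 1 without a filter (skeletal muscle, adjusted p = 0.014), 2 with the stricter filter, 2 with array weights and 1 without wildtype 2 and knockout 1. It ranged from 0 to 3 with 1 array left out. These counts are from camera with the preset correlation, and with an estimated correlation 0 lists passed in each of these settings (lowest adjusted p = 0.61, without a filter). Different lists passed in these settings, among them rod genes in 3, oxidative phosphorylation in 4 and lens in 3.

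With the replicate number as a block, the replicate block fit gave 2 probe sets (adjusted p = 0.0010 and 0.0066) and 0 lists. Pairing by number is unsettled: deviations of same-numbered arrays correlated at 0.18, -0.03 and 0.08, and other pairs at -0.29 to 0.26.

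Among named genes that did not pass, signs turned in 25 of the 1929 cases. With 4 members per list (2 was set after the runs), 80 of 3242 turned. Many cases could not, as where only the filter or variance model changed. Without rescaling, Sag (0.13), Aipl1 (0.055), Cdhr1 (0.12), Cebpd (0.018), Irf1 (0.11), Ngp (0.21), Krt18 (0.15), Fxyd7 (0.12), Atp5b (0.029), Pfkm (0.072) and Rpl11 (0.094) became positive, as the median of all probe sets moved to 0.29, and Epha2 passed (1.49). Ngp was 0.052 with quantile and 0.041 with median scaling, 0.00010 and 0.00019 with the lens and Xist covariates, and ranged from -0.14 to 0.070 with 1 array left out, positive without wildtype 1, knockout 2 or knockout 3. Fxyd1 was -0.11 with array weights and ranged from -0.18 (without knockout 1) to 0.53 with 1 array left out. Without wildtype 2 and knockout 1, Gja1 (-0.093), Ttr (-0.027), Dct (-0.016), Fxyd1 (-0.074) and Uty (0.20) turned. With 1 array left out, 9 to 17 named probe sets moved over 1.5 times or turned. Without wildtype 1 the 10 included Gfap (0.31), Cx3cr1 (0.20), Irf1 (-0.11), Gjd2 (-0.26), Lhx1 (0.44), Ttr (1.05), Dct (0.61), Cryga (0.42) and Crygf (0.034). Without wildtype 2 the 14 included Irf1 (-0.11), Lhx1 (0.062), Bub1b (0.47), Eng (-0.27), Gja1 (0.28), Ttr (0.15), Dct (0.054), Cryga (0.35), Tnfrsf1a (0.71), Casp9 (0.23), Rps27 (-0.23), Kdm5c (0.55) and Uty (-0.056). Without wildtype 3 the 15 included Gfap (0.043), Serping1 (0.16), Irf1 (-0.32), Neurod2 (0.18), Notch1 (0.22), Cryga (1.62), Crygf (1.26), Des (-0.55), Tnfrsf1a (0.26), Calr (0.11), Kdm5c (0.13) and Uty (-0.43). Without knockout 1 the 17 included Opn1mw (-0.45), Cdhr1 (-0.12), Gng13 (0.28), Irx5 (0.17), Gfap (0.063), C1qb (0.24), Ifitm3 (0.033), Irf1 (-0.30), Rrm1 (-0.24), Gja1 (0.30), Zic1 (0.16), Jund (0.32), Syt1 (-0.35), Crb1 (-0.16) and Uty (-0.026). Without knockout 2 the 11 included Gfap (0.32), C1qb (0.66), Ifitm3 (0.57), Irf1 (-0.062), Dct (0.54), Crygf (1.07), Casq1 (-0.17), Slc2a1 (0.15) and Uty (-0.46). Without knockout 3 the 9 included Cebpd (-0.0087), Septin4 (0.19), Notch1 (0.19), Dct (0.21), Cryga (0.40), Crygf (0.39) and Krt18 (-0.088).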

Other observations

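The tests of the genotype for knockout array 1, of the crystallins and of Hbb-b2 were chosen after the result was seen; those of array quality, of other splits and of probe sets of one gene were set before. The comparison of that genotype ratio with the other arrays, and the bound for the crystallins, were also set after. The array quality test was first read by its value and, after that value was seen, by its bootstrap interval.

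Below the signal filter, an Hbb-b2 probe set (a beta-globin gene, singled out after its values were seen) had scaled signals of 7.48, 3.69 and 6.14 in wildtype and 51.9, 41.3 and 48.5 in knockout arrays, higher in 3 of 3. Without the filter its limma adjusted p was 0.10. Blood left in the tissue is argued against: over 21 other globin and red cell probe sets, most of them dim, the median log2 fold change was -0.061. The 3 bright ones, which name several globin genes, had 0.09, 0.03 and 0.07. A strain variant under the probes may account for it and stays open, since the other Hbb-b2 probe set (log2 fold change 0.14) lay near the floor; chance over 22626 probe sets also stays open.

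Crystallin signal differed between arrays. Cryaa had 5.87, 4.45 and 251 in wildtype and 17.2, 12.6 and 130 in knockout arrays, and Cryba1 had 19.9, 6.68 and 398 against 65.6, 29.1 and 176. Lens list means ran from -0.96 to 1.23 among the wildtype arrays alone, which argues against the knockout as the source of that part of the spread. Beyond that part, a knockout effect cannot be told apart from carried-over tissue. The highest knockout array lay -0.52 on the log2 scale relative to the highest wildtype array, within the SD between arrays of 0.95, and without wildtype array 3 the lens list passed camera with the preset correlation (adjusted p = 2.1e-05) but not with an estimated one (0.88), in a setting that removes the wildtype array that went against the effect. Lens and other anterior eye tissue carried over in dissection may account for it and stays open. Of 7 keratin genes in the cornea list, 3 (Krt5, Krt15 and Krt19) were highest in the same 2 arrays, with Krt15 at 161 and 121 there and at most 6.56 elsewhere, while Krt8, Krt12, Krt14 and Krt18 were not, by the brightest probe set of each gene. A dimmer probe set of Krt8 and a dimmer one of Krt14 were also highest there. The lens membrane gene Mip stayed at or under 14.4 on every array, so this source is not settled.

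Knockout array 1 was at least 2-fold away from wildtype arrays 1 and 2 on 871 probe sets, 728 of them lower. On these, knockout arrays 2 and 3 were shifted from wildtype array 3 by 0.15 of its median shift (bootstrap interval over probe sets 0.13 to 0.17). With wildtype array 1 or 2 in the place of wildtype array 3, and probe sets chosen anew, the ratio was 0.014 or 0.11. The probe sets were chosen by knockout array 1 itself, and the ratio taken in the same way for the other 5 arrays ran from -0.24 to 0.25. This ratio therefore cannot tell genotype apart. Knockout array 1 correlated with knockout arrays 2 and 3 at 0.928 and 0.933, and with wildtype arrays 1 to 3 at 0.936, 0.925 and 0.914. It was thus closer to both knockout arrays than to wildtype arrays 2 and 3, but not than to wildtype array 1. Knockout arrays 2 and 3 correlated with the wildtype arrays at 0.958 to 0.979, so the knockout arrays did not stand apart as a group. That argues against the shared genotype as the whole reason. A smaller part from the shared genotype cannot be told apart. An effect of genotype in that sample alone was not tested. The deviations of knockout array 1 correlated at 0.32 (0.28 to 0.36) between 2 probe sets of the same gene, over 2935 genes, against 0.05 to 0.29 in the other arrays. That interval overlaps the highest of the others, so array quality cannot be told apart from a change of transcripts in that sample.

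The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2 probe sets past the threshold and the highest other gave 1, so 1 split of 10 gave as many. For 1.5-fold differences without overlap, the real split gave 219 and the highest other 373, and 3 splits of 10 gave as many. Log2 fold changes of 2 probe sets of one gene correlated at 0.11 (0.07 to 0.16) in the real split, below the 0.12 to 0.39 of the other 9. The interval, taken over genes and not over arrays, reaches into that range. The other splits mix both groups and carry shifts of single arrays, so they are no reference free of differences. A broad group difference shared by probe sets of one gene was not seen above those splits. The test cannot exclude one, and differences in few genes also stay open.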
